A study of Mus musculus with 5 samples.

How the data were processed

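RNA was measured by sequencing in hippocampus of 3-month-old male mice, in 2 wild-type (WT) libraries and 3 SORLA TG libraries. They are called by their titles, WT_82 and WT_87 for WT and S_TG91, S_TG92 and S_TG1301 for SORLA TG. SORLA is the sorting receptor encoded by SORL1, a member of the VPS10 receptor family, and SORLA TG mice overexpress the human protein. Groups and replicate numbers were taken from the sample titles and genotype labels. The labels give no batch. The extract protocol in the labels describes motor cortex of postnatal day 22 and disagrees with the tissue and age labels, which were used here because the design text repeats them. The strain label holds a bare letter that names no strain.

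The authors deposited FPKM values, 1 column per library, for 35275 genes, with gene identifiers, symbols, coordinates and a gene length in bases, per the file headers. The genome build is mm10, per the submitters' processing notes, which also name DESeq2 without its step, and libraries were made with an NEBNext Ultra RNA kit, per the labels' protocols. The aligner, the counter, the gene annotation, their versions and the use of strand are not given in the sources used here. Reads shared between near-identical genes, such as the alpha-globin or beta-globin copies, and between overlapping or antisense genes may therefore be split in ways that cannot be checked here.

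FPKM multiplied by gene length was a whole multiple of 1 step per library for every gene, with a largest deviation from a whole number of 5.1e-05 reads. This gave the reads behind each value and the library totals: 23067120 and 25846761 for WT_82 and WT_87, and 22195798, 21746611 and 21802098 for S_TG91, S_TG92 and S_TG1301. At these depths a gene length of 2 kb with 0 reads allows up to 0.058 to 0.069 FPKM, taking 3 reads as the limit. The limit covers counting error only. No columns of other samples were present.

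All tests were run in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1). The 14738 genes with a mean of at least 0.5 FPKM over the 5 libraries were tested with a linear model with 1 term for genotype, a variance trend and 2-sided p-values, adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are SORLA TG minus WT on the log2(FPKM + 1) scale, which understates the change of genes of low FPKM. FPKM values are given as mean ± SD. An exact permutation test of 2 against 3 libraries has a smallest 2-sided p of 0.2, so no single gene can pass 0.05 in such a test. Nothing in the sources used here says how the libraries relate to litters or extraction days. The p-values of single genes therefore measure the spread between these libraries.

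Before the data were examined, 18 gene lists and 21 lists of cell type or region markers were fixed, together with the test, the alternatives and the rule for naming genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, 2-sided, adjusted over the 39 lists. Member counts are given past the threshold over all genes and adjusted over the list alone. Camera with a correlation estimated per list and the rotation test fry were alternatives. At the preset value the genes of a list count as nearly independent, so its p-values do not measure the spread between mice. The estimated correlation was 0.966 for striatum, 0.975 for choroid plexus and 0.898 for myelin genes. Of 694 list symbols, Drd1 alone had no row, since the deposited symbols use its older name Drd1a, and it stayed out of the list. The naming rule took Sorl1, then up to 12 rises and 12 falls past the threshold. Where these came to fewer than 20, the genes of smallest p with a mean of at least 1 FPKM were added. In each list past its test and in the immediate early genes, up to 6 members by smallest p were named, and Fos, Egfr, Xist, Ddx3y and Eif2s3y were named as values. Genes outside the rule are marked where they appear, and a few genes that the rule names are not reported here.

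The alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 1 FPKM, scaling by the median of ratios, no variance trend, a robust prior, library weights, a threshold of 0.1 and each library left out in turn. With 1 WT library left, its spread is assumed to be that of the SORLA TG libraries. Chosen after seeing the data were limma-voom on the recovered reads and a fit without the genes of the striatum, choroid plexus, ependymal, myelin and blood lists.

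The gene and list tests were tested on simulated data: reads drawn from the real means and depths with the median dispersion between libraries of 1 group, 0.0128, in 5 simulations of 3 against 2 libraries with about 14743 genes tested. Of genes changed 2-fold, 83.2% (416 of 500) were called, and of genes changed 4-fold, 94.8% (474 of 500), with 84 unchanged genes called over the 5 simulations. A list of 30 genes shifted by 0.5 log2 units was called in 5 of 5 simulations and 0 of 190 unchanged lists were called. The simulated genes varied independently of each other, which the genes of real lists need not do. All genes and both groups were given the same dispersion, while the real WT pair was more spread than the SORLA TG pairs. The shares called in the simulations therefore need not hold for the real libraries, and 0 calls there do not exclude 2-fold changes.

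No libraries held identical values. The chi-square per degree of freedom between libraries of 1 group was 58 for the WT pair and 17.4 to 27.6 for the SORLA TG pairs, so none was counted as a duplicate.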

Results

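Hippocampal RNA of 2 WT and 3 SORLA TG male mice, all 3 months old, was compared to ask which transcripts differ when human SORLA, a sorting receptor for proteins such as the amyloid precursor protein, is overexpressed. The libraries held 21746611 to 25846761 reads over genes, and 12789 to 13131 genes reached 1 FPKM in each. The 50 most abundant genes took 13.5% to 14.4% of reads. Mitochondrial transcripts took 4.48% and 4.47% of reads in WT and 4.21%, 4.74% and 3.05% in SORLA TG. Across tested genes, which are not independent replicates, the 2 WT libraries were the least alike pair, with a Pearson r of 0.9686 on the log scale, against 0.9841 to 0.9879 between SORLA TG libraries.

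Mouse Sorl1 (ENSMUSG00000049313, chromosome 9, 41964720 to 42124297, mm10) stood at 72.8 and 60.3 FPKM in the WT libraries WT_82 and WT_87 and at 91.1, 70.4 and 79.1 FPKM in the SORLA TG libraries S_TG91, S_TG92 and S_TG1301. Means were 66.6 ± 8.78 FPKM (SD, n = 2) and 80.2 ± 10.4 FPKM (SD, n = 3). The log2 difference of 0.26 (SE 0.14) was within the spread of the libraries (limma adjusted p = 0.718). The transgene is human and the values are on mouse genes, so mouse Sorl1 records only those transgene reads that align to it, and this value is no full check of the genotype labels. Xist, the RNA of the inactive X chromosome of females, was at 0.073 FPKM or less in each library. The Y-linked genes Ddx3y and Eif2s3y were at 7.97 to 11.5 FPKM and 4.15 to 7.42 FPKM, as in males.

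No gene passed the threshold between genotypes in limma, with 0 higher, 0 lower and a smallest adjusted p of 0.425. An unadjusted p under 0.05 was reached by 1072 genes, 7.3% of those tested, 400 higher and 672 lower in SORLA TG. The libraries of the groups did not overlap for 3422 genes, 23.2%, where chance gives 20%. With limma-voom on the recovered reads the counts were again 0 past the threshold, and 1047 at an unadjusted p under 0.05. Calls appeared when a WT library was left out: 17 genes higher and 97 lower without WT_82, and 3 higher and 8 lower without WT_87, with Ecel1 the 1 gene in both sets.

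Of the 20 genes of smallest p, 19 were lower in SORLA TG and 1 was higher. Their adjusted p ran from 0.425 to 0.554. The groups' libraries did not overlap for any of them, which the choice by smallest p nearly fixes. Of the 1072 genes with an unadjusted p under 0.05, 1043 did not overlap. Six3 (ENSMUSG00000038805, chromosome 17, 85613608 to 85629302), a homeobox factor of forebrain development, had 3.53 and 6.31 FPKM in WT and 0.073, 0.062 and 0.337 FPKM in SORLA TG, a log2 difference of -2.32 (SE 0.24). Sp9 (ENSMUSG00000068859, chromosome 2, 73271925 to 73284706), a zinc finger factor of GABAergic neurons, was at 3.60 ± 0.159 FPKM (SD, n = 2) against 1.36 ± 0.145 FPKM (SD, n = 3). Ecel1, a membrane metalloprotease, was at 4.87 ± 2.13 FPKM in WT and 0.652 ± 0.0824 FPKM in SORLA TG. Ano2, a calcium-activated chloride channel, was at 2.75 ± 0.663 and 0.469 ± 0.141 FPKM, and Pld5, of the phospholipase D family, at 3.06 ± 0.698 and 0.448 ± 0.031 FPKM. Cryab, a small heat shock protein, was at 45.4 ± 6.36 and 23.0 ± 3.80 FPKM. Zbtb16, a zinc finger transcription factor and the higher gene of the 20, was at 14.1 ± 2.12 and 24.96 ± 2.09 FPKM, a log2 difference of 0.78 (SE 0.13). The neighbouring genes C030048H21Rik and 4932418E24Rik on chromosome 2 were at 21.0% and 21.6% of the WT mean. Further genes of the 20, Strip2, Fam222a, Scube3, 1700013F07Rik, Gm10282, the secreted guidance factor Sema3f, the heparan sulfate proteoglycan Sdc2, Plekhg3, Rftn1 and the lysosomal sulfatase Arsg, were at 29.9% to 63.9% of the WT mean. Without WT_82, 8 of the 20 passed the threshold, and without WT_87, 1 did.

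Lists of genes fixed in advance were compared next, to ask whether groups of related genes differed together. At the preset correlation 17 of the 39 lists passed, 9 higher and 8 lower in SORLA TG, and 11 of the 17 were marker lists of cell types or regions. With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.49, and with fry 0 passed, with a smallest adjusted p of 0.301. No member of any list passed the threshold over all genes, so member values below are given as values. Median, mean and test differed in sign for 6 lists, none of them past the threshold.

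The list differences of greatest size were in markers of striatum, choroid plexus and ependyma, tissues that adjoin the hippocampus or lie in the ventricles, and 2 of the 3 rested mainly on 1 WT library each. All 10 measured striatal markers were lower in SORLA TG, with a median log2 difference of -2.26 (camera adjusted p = 3.86e-07, adjusted p = 0.609 with an estimated correlation). The dopamine receptor Drd2 was at 49.6 FPKM in WT_87, 4.09 FPKM in WT_82 and 1.34 to 1.92 FPKM in SORLA TG. Ppp1r1b, the phosphatase inhibitor of dopamine-responsive neurons, was at 378 FPKM in WT_87 and 23.6 to 46.9 FPKM in the remaining libraries. Over the list, WT_87 was a median 15.7-fold above the mean of the other libraries on FPKM + 1, and without it the median difference was -0.41 (adjusted p = 0.000919), against -4.1 without WT_82. Isl1, a homeobox factor of striatal and septal neurons, was the 1 member past the threshold adjusted over the list alone, at 1.12 and 1.84 FPKM in WT and 0, 0 and 0.091 FPKM in SORLA TG.

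All 15 choroid plexus markers were lower in SORLA TG as well, with a median of -1.64 (camera adjusted p = 6.58e-06, adjusted p = 0.689 with an estimated correlation) and 0 past the threshold adjusted over the list alone. The transthyretin gene Ttr was at 1023 FPKM in WT_82 and 56.1 FPKM in WT_87, and at 11.5, 22.1 and 158 FPKM in S_TG91, S_TG92 and S_TG1301. Enpp2, the secreted lipid enzyme autotaxin, was at 935 and 136 FPKM in WT and 42.5, 56.9 and 229 FPKM in SORLA TG. Without WT_82 the call was lost, with a median of -0.09 (adjusted p = 0.55), and without WT_87 the median was -3.12. Ependymal markers were lower in 8 of 8 measured members, with a median of -0.91 (camera adjusted p = 3.2e-06, adjusted p = 0.609 with an estimated correlation). Of these, 7 passed the threshold adjusted over the list alone, among them Foxj1, the regulator of motile cilia, at 14.3 and 7.51 FPKM in WT and 2.87, 4.75 and 4.74 FPKM in SORLA TG, and Ccdc153 at 5.67 and 4.56 FPKM against 0.747, 2.79 and 2.49 FPKM. The ependymal list passed with each library left out, and its median was highest without WT_82, -0.54. Its median gene was at 4.29 FPKM in WT_82, the library with choroid plexus genes, and 1.72 FPKM in WT_87. In S_TG91, S_TG92 and S_TG1301 it was at 1.01, 1.62 and 1.41 FPKM.

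**Figure D1:**
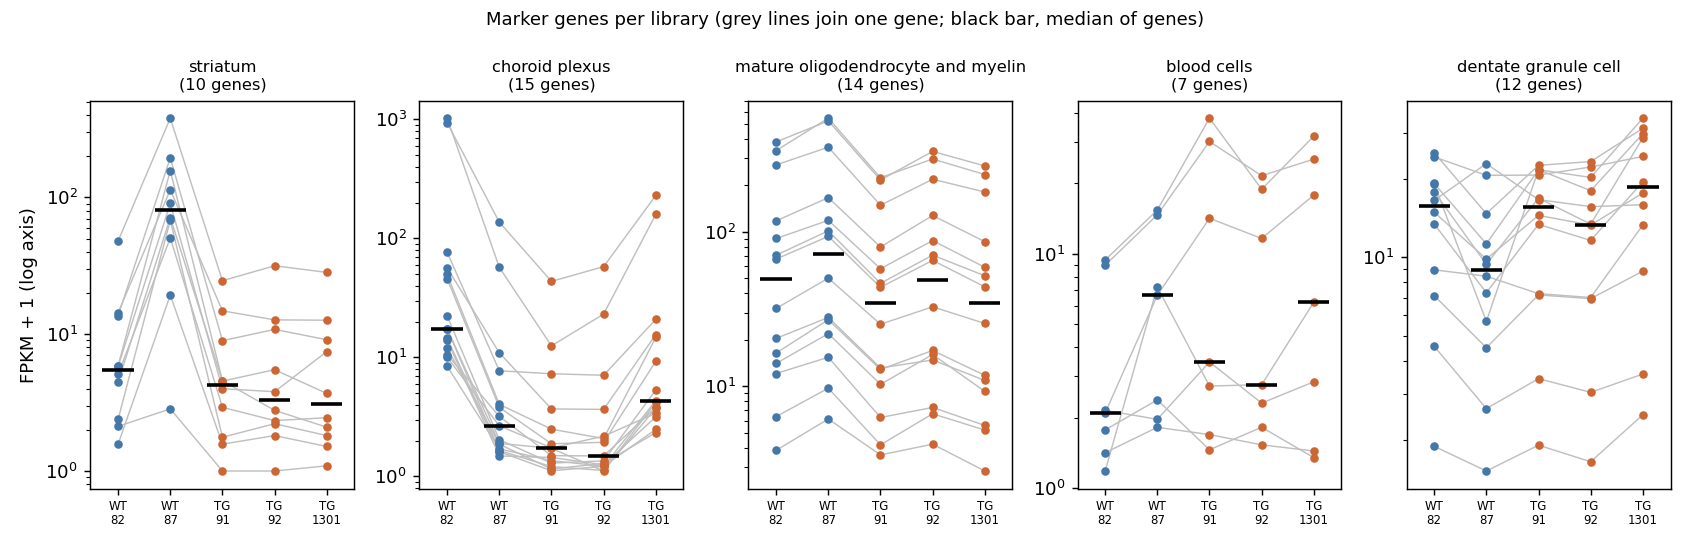
FPKM + 1 on log axes for the measured genes of 5 marker lists in each library, WT in blue and SORLA TG in orange, with grey lines joining a gene across libraries and black bars at the median gene. Striatal genes stand out in WT_87, where Drd2 reaches 49.6 FPKM, and choroid plexus genes in WT_82, where Ttr reaches 1023 FPKM.

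Genes of mature oligodendrocytes and myelin were lower in SORLA TG in 14 of 14 members, with a median log2 difference of -0.62 (camera adjusted p = 2.56e-11, adjusted p = 0.609 with an estimated correlation). Of these, 7 passed the threshold adjusted over the list alone, and the same number was lower in every SORLA TG library than in both WT libraries. Mbp, myelin basic protein, was at 381 and 522 FPKM in WT and 216, 331 and 266 FPKM in SORLA TG. Mobp, a further myelin protein gene, was at 311 ± 57.9 FPKM (SD, n = 2) against 182 ± 35.2 FPKM (SD, n = 3). The myelin list passed with each library left out. Its median was -0.38 without WT_87, the library with striatal genes, and -0.91 without WT_82. Against WT_82 alone, S_TG92 was about level, with a median of -0.0134, while S_TG91 and S_TG1301 had medians of -0.606 and -0.517.

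Oligodendrocyte precursor markers were lower in 9 of 9 members, with a median of -0.25 (camera adjusted p = 0.00131, adjusted p = 0.609 with an estimated correlation). The 2 members past the threshold adjusted over the list alone were Bcas1, at 42.1 ± 8.43 against 24.96 ± 3.66 FPKM, and Sox10, at 22.5 ± 4.63 against 12.9 ± 3.02 FPKM, both also active in mature oligodendrocytes. Pdgfra, the growth factor receptor of precursors, was at 11.8 ± 0.0257 and 10.6 ± 0.682 FPKM. Microglial markers were lower in 12 of 12 members, with a median of -0.23 (camera adjusted p = 0.00243, adjusted p = 0.689 with an estimated correlation) and 0 past the threshold adjusted over the list alone. The microglial genes Siglech and Aif1 were at 73.3% and 70.5% of the WT mean. Without WT_87 both calls were lost, with a median of -0.152 and an adjusted p of 0.139 for precursors and -0.0733 and 0.745 for microglia. Without WT_82 the medians were -0.465 and -0.422. The microglial median was -0.145 without S_TG91 (adjusted p = 0.0578) and -0.368 without S_TG92. Astrocyte markers did not pass, with 8 of 12 lower and a median of -0.04 (adjusted p = 0.828).

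Lists of glutamatergic neurons, CA1 pyramidal cells and dentate granule cells were higher in SORLA TG at the preset correlation, while CA3 pyramidal markers did not pass. The glutamatergic neuron list was higher in 8 of 8 members, with a median of 0.21 (camera adjusted p = 0.0127, adjusted p = 0.604 with an estimated correlation), and its member of smallest p was the vesicular glutamate transporter Slc17a7, at 545 ± 4.93 against 698 ± 76.5 FPKM. CA1 pyramidal markers were higher in 7 of 8 members, with a median of 0.32 (camera adjusted p = 0.0207, adjusted p = 0.689 with an estimated correlation). Dentate granule cell markers were higher in 9 of 12 members, with a median of 0.36 (camera adjusted p = 0.0127, adjusted p = 0.689 with an estimated correlation). Prox1, the granule cell transcription factor, was at 18.1 and 10.2 FPKM in WT and 20.6, 17.0 and 28.7 FPKM in SORLA TG, and C1ql2, a secreted synaptic protein, at 18.1 and 4.68 FPKM against 20.6, 19.2 and 33.0 FPKM. No member of these lists passed the threshold adjusted over the list alone. WT_87, the library with striatal genes, had the lowest list median of the 5 libraries in each, and without it the 3 calls were lost, with adjusted p of 0.157, 0.927 and 0.745 and medians of 0.12, -0.0011 and 0.04, while without WT_82 the medians were 0.332, 0.586 and 0.683. The CA1 call was also lost without S_TG91 (median 0.171, adjusted p = 0.281) and the dentate call without S_TG1301 (median 0.204, adjusted p = 0.449).

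Other neuronal markers did not pass. Medians were 0.08 for pan-neuronal genes (adjusted p = 0.141), 0.01 for CA3 pyramidal cells (adjusted p = 0.972), -0.14 for newborn neurons and progenitors (adjusted p = 0.828), 0.19 for subiculum and entorhinal cortex (adjusted p = 0.388), 0.01 for neocortical layers (adjusted p = 0.799) and -0.04 for thalamus (adjusted p = 0.733). The neocortical median was -0.378 without WT_82 and 0.245 without WT_87. The subiculum and entorhinal list passed without S_TG1301 (median 0.447, camera adjusted p = 0.0186), and its median was -0.032 without S_TG91. The list of GABAergic interneurons had 6 higher and 6 lower members (median -0.01, adjusted p = 0.598). Its 2 members past the threshold adjusted over the list alone, named after their values were seen, were Gad2, a GABA synthesis enzyme, at 51.0 ± 5.43 FPKM in WT and 29.8 ± 3.93 FPKM in SORLA TG, and Slc32a1, the vesicular GABA transporter, at 36.7 ± 8.98 and 19.9 ± 4.88 FPKM. Gad2 and Slc32a1 serve GABAergic neurons in general, so their values do not show fewer hippocampal interneurons. Whether tissue with the striatal genes of WT_87 contributed was not tested. The list median was 0.0082 without WT_82 and 0.217 without WT_87. Sst, a peptide gene of interneurons named after its values were seen, was at 49.4 ± 5.59 and 60.5 ± 32.2 FPKM.

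Synaptic genes were higher as lists. Glutamatergic synapse genes were higher in 20 of 29 members, with a median of 0.13 (camera adjusted p = 0.00127, adjusted p = 0.49 with an estimated correlation). Examples were the NMDA receptor subunits Grin2b, at 43.1 ± 4.92 FPKM in WT and 58.7 ± 4.32 FPKM in SORLA TG, and Grin2a, at 33.9 ± 4.16 and 49.5 ± 10.2 FPKM, the scaffold Shank1, at 217 ± 2.94 and 274 ± 13.8 FPKM, and the receptor Grm2, at 9.89 ± 3.86 and 17.8 ± 2.72 FPKM. Presynaptic vesicle genes were higher in 17 of 22 members, with a median of 0.14 (camera adjusted p = 0.00202, adjusted p = 0.49 with an estimated correlation), among them synaptophysin, Syp, at 288 ± 26.3 and 352 ± 11.8 FPKM. Neurite growth genes were higher in 22 of 30 members, with a median of 0.05 (camera adjusted p = 0.0268, adjusted p = 0.609 with an estimated correlation). Within that list the Nogo receptor Rtn4r, which restrains growth, was at 23.0 ± 3.81 and 36.1 ± 4.30 FPKM, while Gap43, a growth cone protein, was at 67.6 ± 11.0 and 48.0 ± 12 FPKM. No member of the 3 lists passed the threshold adjusted over the list alone. Without WT_82, the library with choroid plexus genes, the calls were lost, with adjusted p of 0.0842, 0.366 and 0.281, and medians of 0.135 for the glutamatergic synapse, 0.09 for presynaptic and -0.01 for neurite genes. Without S_TG91 the neurite call was lost too (median 0.00586, adjusted p = 0.167), and its median was 0.0887 without WT_87 and 0.112 without S_TG1301. The presynaptic median was 0.0834 without S_TG92. Beside these lists, glutamatergic neuron markers had a median of 0.211 and myelin genes of -0.625. GABAergic synapse genes did not pass (median 0.10, adjusted p = 0.163).

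Immediate early genes, which neurons induce within minutes of activity, were higher in 24 of 30 members, with a median of 0.11 (camera adjusted p = 0.00412, adjusted p = 0.644 with an estimated correlation). None passed over all genes, and 0 passed adjusted over the list alone. The list was fixed with prior knowledge of the study's published interest in Fos, so its direction is not fully independent evidence. Npas4 was at 2.26 and 2.24 FPKM in WT and 3.55, 5.33 and 4.13 FPKM in SORLA TG, a log2 difference of 0.70 (SE 0.17). Btg2 was at 2.79 ± 0.551 and 4.57 ± 0.722 FPKM, Gadd45b at 2.44 ± 0.489 and 3.92 ± 0.458 FPKM, Ier2 at 2.30 ± 0.594 and 3.501 ± 0.477 FPKM and Fosl2 at 11.9 ± 0.0049 and 15.3 ± 1.55 FPKM. Inhba, an activin subunit, was lower, at 9.02 ± 3.63 and 5.10 ± 0.392 FPKM, with a log2 difference of -1.05 without WT_82 and -0.290 without WT_87. Fos was at 2.37 and 3.10 FPKM in WT and 2.61, 6.24 and 5.42 FPKM in SORLA TG (log2 difference 0.57, SE 0.30, adjusted p = 0.718), with S_TG91 inside the WT range. Arc, named after its values were seen, had 20.49 and 27.9 FPKM in WT and 18.6, 62.6 and 55.6 FPKM in SORLA TG. Beside this list, glutamatergic neuron, CA1 and dentate markers had medians of 0.211, 0.323 and 0.355 and myelin genes of -0.625. Without WT_82 the list was not called (adjusted p = 0.294), and its median was 0.22 without WT_82, 0.24 without WT_87, 0.25 without S_TG91, 0.084 without S_TG92 and 0.0791 without S_TG1301.

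**Figure D2:**
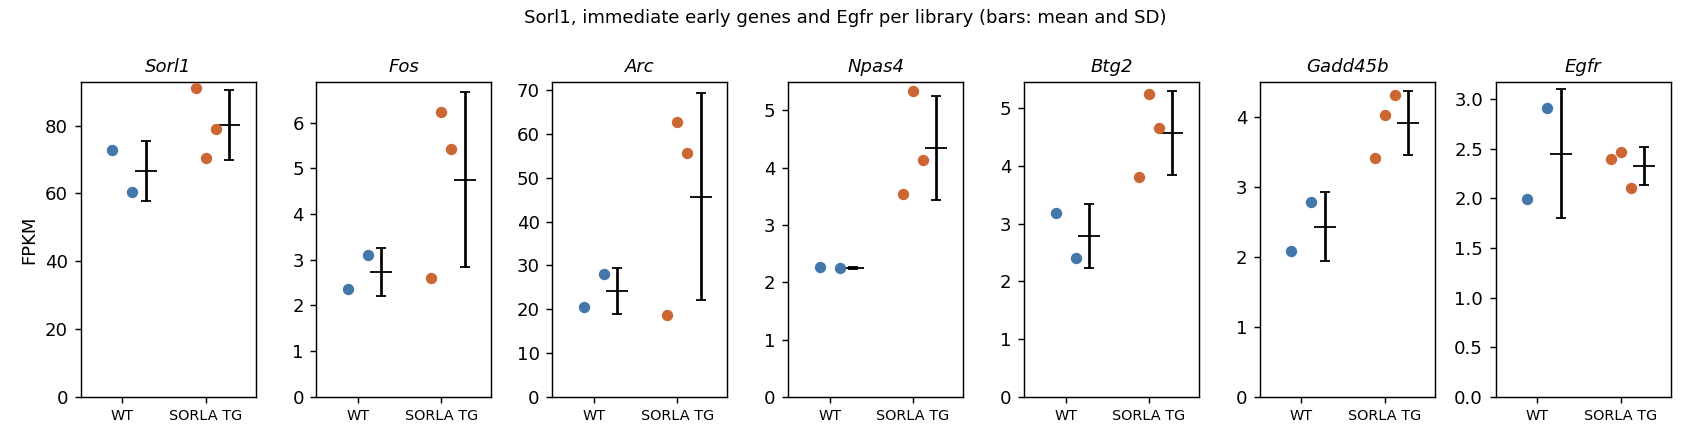
FPKM of Sorl1, 5 immediate early genes and Egfr in each WT library (blue points) and SORLA TG library (orange points), with bars at the mean and SD of each group. Npas4, Btg2 and Gadd45b, named for their small p, do not overlap between groups, while Sorl1, Fos, Arc and Egfr do. Over the whole immediate early list 8 of 30 members do not overlap, beside 23.2% of all tested genes.

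Components of the EGFR and ERK pathway did not pass (10 of 24 higher, median -0.04, adjusted p = 0.626), nor did ERK feedback genes (10 of 15 higher, median 0.07, adjusted p = 0.358). Egfr was at 1.99 and 2.91 FPKM in WT and 2.40, 2.47 and 2.10 FPKM in SORLA TG. Genes of VPS10 receptors and retromer sorting, the family and partners of SORLA, had 11 of 24 members higher and a median of -0.01 (adjusted p = 0.828).

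Heat shock and endoplasmic reticulum stress genes were lower in SORLA TG in 17 of 21 members, with a median of -0.25 (camera adjusted p = 0.000274, adjusted p = 0.616 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Hspa5, a chaperone of the endoplasmic reticulum, was at 168 and 124 FPKM in WT and 95.2, 99.8 and 99.9 FPKM in SORLA TG, Hsp90b1 at 78.7 ± 9.87 and 58.0 ± 1.79 FPKM, and Calr, the calcium-binding chaperone, at 182 ± 23.2 and 132 ± 9.002 FPKM. The call was lost without WT_82, the library with choroid plexus genes (median -0.13, adjusted p = 0.121), and the median was -0.41 without WT_87. Genes of amyloid precursor processing and Alzheimer's disease risk were lower in 24 of 30 members, with a median of -0.14 (camera adjusted p = 0.00507, adjusted p = 0.49 with an estimated correlation) and 0 past the threshold adjusted over the list alone. Psenen, a gamma-secretase subunit, was at 17.2 ± 0.0908 and 12.1 ± 3.57 FPKM. Adam17, a membrane protease, was at 4.24 ± 0.0861 and 3.28 ± 0.319 FPKM, and Picalm, a clathrin adaptor, at 43.1 ± 4.53 and 36.5 ± 0.394 FPKM. Beside this list, microglial, precursor and myelin genes had medians of -0.227, -0.249 and -0.625. The call of the amyloid list was lost without WT_82 (median -0.09, adjusted p = 0.0708) and without WT_87 (median -0.109, adjusted p = 0.0575).

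Blood cell genes were higher in SORLA TG in 5 of 7 measured members, with a median of 0.46 (camera adjusted p = 0.00491, adjusted p = 0.616 with an estimated correlation). The 3 past the threshold adjusted over the list alone were globins: Hba-a1, at 7.94 and 13.7 FPKM in WT and 29.1, 20.525 and 24.3 FPKM in SORLA TG, Hba-a2, at 1.10 and 5.66 FPKM against 13.2, 10.6 and 16.8 FPKM, and Hbb-bs, at 8.41 and 14.4 FPKM against 36.9, 17.8 and 30.8 FPKM. Copies of each globin are nearly identical, so their separate values are uncertain. Without WT_82 the call was lost although the median was 0.525 (adjusted p = 0.281), and the median was 1.51 without WT_87. Genes of meninges and fibroblasts were higher in 10 of 12 members, with a median of 0.30 (camera adjusted p = 0.00446, adjusted p = 0.689 with an estimated correlation). Fmod, fibromodulin, was the 1 member past the threshold adjusted over the list alone, at 1.70 ± 0.600 and 4.08 ± 0.802 FPKM. Without WT_87 the meningeal call was lost and the median turned to -0.14 (adjusted p = 0.744), and the median was 0.68 without WT_82 and 0.199 without S_TG91. Neither endothelial genes (9 of 12 lower, median -0.12, adjusted p = 0.142) nor pericyte and smooth muscle genes (median -0.06, adjusted p = 0.828) passed with all libraries. The endothelial list passed without S_TG91 (median -0.184, camera adjusted p = 0.0173), and its median was -0.0304 without S_TG1301.

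The remaining lists did not pass. Medians were 0.12 for Eph receptors and ephrins (adjusted p = 0.388), -0.06 for neurotrophic factors and receptors (adjusted p = 0.972), -0.01 for cholesterol and lipoprotein genes (adjusted p = 0.453) and -0.01 for interferon and antigen presentation (adjusted p = 0.849). Nuclear genes of oxidative phosphorylation had a median of 0.02 (adjusted p = 0.626), mitochondrially encoded genes -0.14 (adjusted p = 0.388), with S_TG1301 lowest, and cytosolic ribosomal protein genes -0.01 (adjusted p = 0.51). Without WT_82 and WT_87 in turn, medians were -0.0401 and 0.0516 for oxidative phosphorylation and -0.0889 and 0.051 for ribosomal protein genes. Mitochondrially encoded genes passed without S_TG92 (median -0.223, camera adjusted p = 0.0115), and their median was 0.0312 without S_TG1301. Neighbours of the Rosa26 locus on chromosome 6 had 28 of 53 members higher and a median of 0.02 (adjusted p = 0.587).

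**Figure D3:**
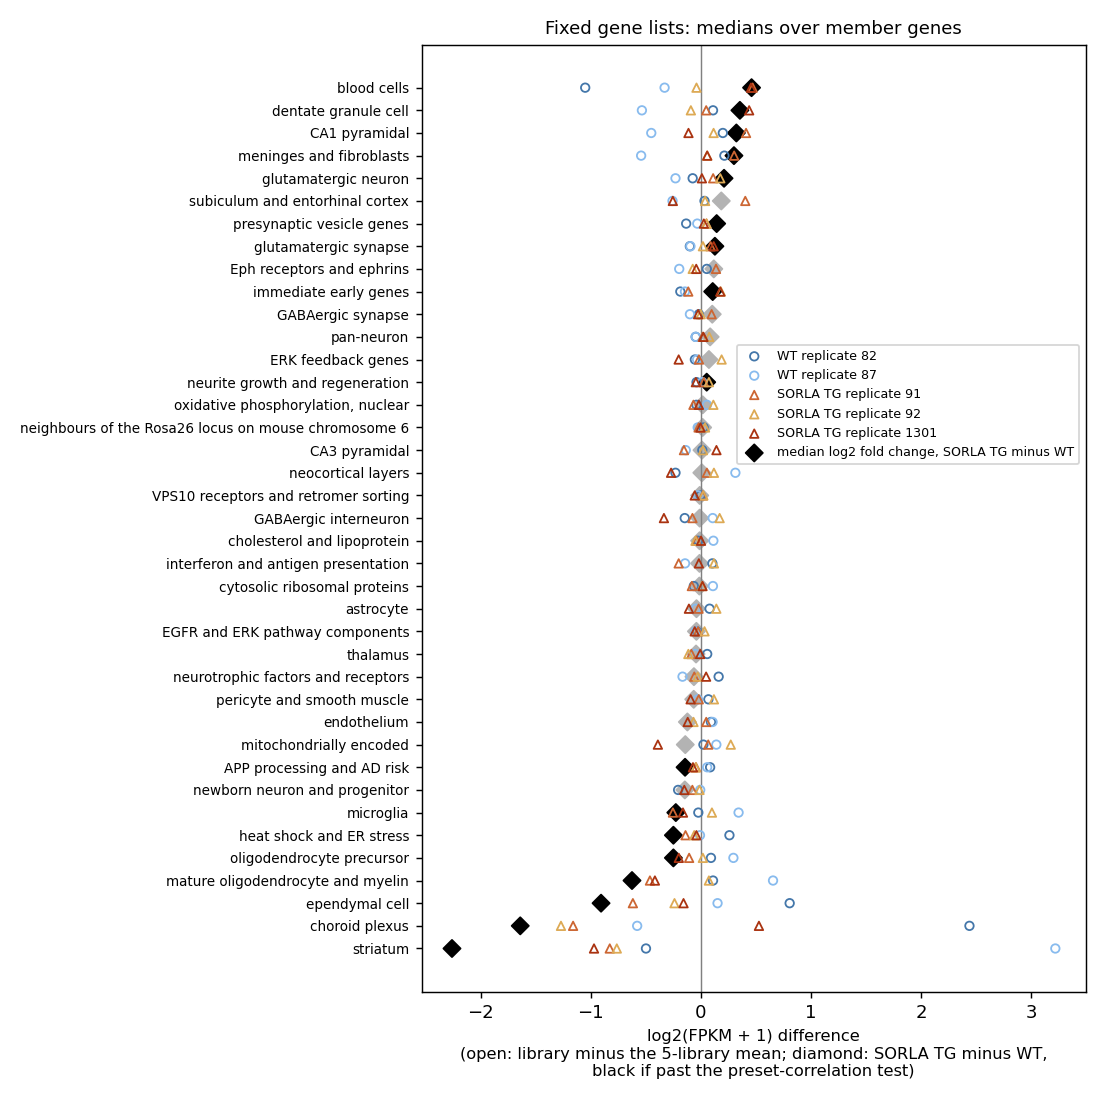
Median log2(FPKM + 1) difference over the members of each of the 39 lists, with diamonds for SORLA TG minus WT, black for the 17 lists past the preset-correlation test and grey for the others, and open symbols for each library minus the mean of the 5 libraries. The medians range from -2.26 for striatum to 0.46 for blood cells, and WT_87 and WT_82 lie far to the right for striatum and choroid plexus.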

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

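The 0 calls in genes held under each alternative of pseudocount, filter, scaling, prior, weights and threshold, in limma-voom and without the genes of the 5 marker lists (the last 2 chosen after seeing the data), with smallest adjusted p of 0.24 to 0.499. The planned tests for counts on the recovered reads, edgeR and DESeq2, were not run, and limma-voom was run on those reads. Leaving out 1 library gave 0 to 17 genes higher and 0 to 97 lower, with calls in the fits with 1 WT library, whose spread is then assumed. Sorl1 kept its direction throughout, at 0.131 to 0.397 over left-out libraries. Against 17 lists past the threshold, 17 passed in limma-voom and 16 without a filter on low values. Once the 5 marker lists, all among the 17, were left out, 12 of the 12 remaining passed. With 1 library left out, 10 to 18 lists passed, not all of them among the 17. Of the 17, 9 passed in the same direction without WT_82. Without WT_87, 10 did, and 1 of the others had the opposite direction. Without S_TG91, S_TG92 and S_TG1301 in turn, 14, 17 and 16 of the 17 passed in the same direction. Finally, 0 lists passed with an estimated correlation and 0 with fry. The last 2 allow for the correlation between genes of a list, but a high correlation does not account for every lost call. For the glutamatergic synapse, presynaptic, amyloid and glutamatergic neuron lists the estimates were 0.00303, -0.00478, -0.0185 and -0.0791, below the preset value. Their camera adjusted p with these estimates were still 0.49, 0.49, 0.49 and 0.604. The remaining called lists had estimates above the preset value. With an estimated correlation, camera uses no more than the 3 residual degrees of freedom of the gene model, far fewer than at the preset value. Fewer degrees of freedom raise p-values, also for lists with low estimates. How much of each loss came from this was not tested separately. Striatum, myelin and ependymal lists passed with each library left out.

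Some log2 differences, none past the threshold over all genes, reversed with a library left out. Lowest values, without WT_87, and highest, without WT_82, were -0.00650 and 0.694 for Neurod2, -0.0885 and 0.504 for Neurod6, -0.0220 and 0.659 for Wfs1, -0.275 and 0.932 for Dcn, -0.0352 and 0.705 for Col1a2 and, as a mean, -0.15 and 0.656 for the meninges list. Lowest without WT_82 and highest without WT_87 were -0.165 and 0.497 for Tbr1, -0.499 and 0.00113 for Vcan, -0.237 and 0.152 for Egfr (0.00600 without S_TG1301) and -1.001 and 1.606 for Hbb-bt (-0.0899 without S_TG1301). Man1a was at -0.526 without WT_87 and 0.0706 without WT_82. For the changed counts and for the reversals, the cause was not tested. No paired analysis was possible because the groups share no replicate numbers.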

Other observations

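The tests of explanations below were chosen after the results were seen, except the counts over splits of the libraries.

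Beyond the striatal and choroid plexus lists, the genes called with 1 WT library left out, which fall outside the naming rule, divide by library. Without WT_82, all 10 measured striatal markers were among the genes called lower, together with Drd1a, at 29.2 FPKM in WT_87 and 0.885 to 1.80 FPKM in the other libraries, and Rarb, the retinoic acid receptor, at 12.3 against 1.13 to 1.30 FPKM. Without WT_87, the 8 genes called lower included Zic1 and Zic2, zinc finger factors of dorsal and midline brain, at 29.9 and 32.5 FPKM in WT_82 and at most 6.60 and 9.82 FPKM in the other libraries. Htr2c, the serotonin receptor of choroid plexus and neurons, was at 19.1 FPKM in WT_82 and 3.26 to 5.41 FPKM elsewhere, and the imprinted gene Dlk1 at 6.36 and 0.416 to 0.68 FPKM. Among the 3 called higher, Rpl23a was at 18.5 FPKM in WT_82 and 43.0 to 52.6 FPKM elsewhere, although ribosomal protein genes have many near-identical copies that can share reads. Some genes were higher in both WT libraries. Six3 was at 3.53 FPKM or more in both and at most 0.337 FPKM in SORLA TG. Ecel1 was at 3.35 FPKM or more in both and at most 0.728 FPKM in SORLA TG. Isl1 of the striatum list had the same pattern, at 1.12 FPKM or more in both and at most 0.091 FPKM in SORLA TG. For such genes, genotype and tissue taken with the WT samples cannot be told apart.

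Striatal genes were high in WT_87. Genotype does not account for the excess over WT_82, since both are WT and differed by a median 3.73 log2 units over 10 genes (quartiles 3.07 to 3.98). Striatal tissue in that library is a candidate source: CA1 and dentate markers differed there by a median of -0.635 log2 units from the other 4 libraries (quartiles -0.949 to -0.225). Its abundant genes Ppp1r1b and Penk reached 378 and 194 FPKM, 7 of the 10 markers also reach 1 FPKM in each remaining library, and none is in another list. For the smaller difference between SORLA TG and WT_82, -0.41 (quartiles -0.929 to -0.145), genotype and tissue taken with the sample cannot be told apart, since 1 WT library is left.

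Choroid plexus genes were high in WT_82. Genotype does not account for its excess over WT_87, since both are WT and differed by a median 3.2 log2 units over 15 genes (quartiles 2.53 to 3.43). For the difference between SORLA TG and WT_87, a median of -0.0886 (quartiles -0.475 to 0.0757), genotype stays open, since all 15 genes were lower in S_TG91 and S_TG92 (medians -0.653 and -0.589) and 0 were lower in S_TG1301 (median 1.14). Choroid plexus tissue carried with some samples may be the source: S_TG1301 held a median 17.9% of the excess of WT_82 over S_TG91 and S_TG92, with quartiles of 16.3% to 21.3% and a range over the 15 genes of 10.4% for F5 to 26.2% for Sostdc1, the latter named after its values were seen. Of the 15 markers, 5 reach 1 FPKM in each remaining library, and none is in another list.

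Myelin genes were lower in SORLA TG in 14 of 14 members. A larger share of neurons in place of all glia in SORLA TG would lower astrocyte markers alike. These had a median of -0.0392 (quartiles -0.0994 to 0.0219), with -0.107 without WT_87 and 0.0436 without WT_82. The myelin medians were -0.38 and -0.913 in those fits. This argues against such a share as the whole cause only if the tissue taken was otherwise alike. The striatal genes of WT_87 and the choroid plexus genes of WT_82 put that in doubt. Fewer oligodendrocytes alone would leave astrocyte markers unchanged, so these markers cannot speak to that. Microglial and precursor markers had medians of -0.227 and -0.249 and glutamatergic neuron markers of 0.211 (camera adjusted p of 0.689, 0.609 and 0.604 with an estimated correlation). Endothelial and pan-neuronal markers, which did not pass, had medians of -0.122 and 0.0849. A larger share of neurons as a part of the cause stays open. Striatal tissue in WT_87 stays open: against WT_82 alone the median was -0.38, with -0.606 for S_TG91, -0.0134 for S_TG92 and -0.517 for S_TG1301, so the libraries do not decide. A lower content of myelin with genotype and a different amount of white matter in the dissected tissue also stay open, and neither was tested.

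A hypothesis on the insertion site was not decided. Were the transgene at the Rosa26 locus, a common site for transgenes, sequence carried along with it might raise the share of differing genes on chromosome 6. There 8.6% of 729 tested genes had an unadjusted p under 0.05, against at most 9.4% on other autosomes and X (Fisher's exact test, 2-sided, adjusted p = 0.396 over 22 chromosomes), an odds ratio of 1.22. Of 53 Rosa26 neighbours, 6 had an unadjusted p under 0.05 and the list did not pass. These misses do not show equal shares, and the labels do not give the site.

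Of the 10 splits of the 5 libraries into 2 and 3, the genotype split was the 1 with as many as 1072 genes of unadjusted p under 0.05, the highest other being 1029 for WT_87 with S_TG92. It was also the 1 with as many as 17 lists past the threshold. Every other split had lists past it as well, from 6 to 13. Many lists thus pass at the preset correlation in splits that do not follow genotype. At the adjusted threshold the genotype split gave 0 genes, and the split of WT_82 with S_TG1301, the libraries highest in choroid plexus genes, gave 2. With 10 splits a share under 0.05 cannot be reached.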
